A study of Rattus norvegicus with 6 samples.

How the data were processed

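RNA was measured by sequencing in 6 samples of rat embryonic hippocampal neurons, 3 given the kinase inhibitor RO48 and 3 given its solvent, dimethyl sulfoxide (DMSO). Per the labels' protocols, libraries followed an Illumina TruSeq protocol and were sequenced on a NovaSeq instrument. Per the submitters' processing notes, STAR (an aligner), HTSeq (a read counter) and the rat genome build Rnor_6.0 were used. Their versions and settings, the annotation release, the use of strand in counting and the normalization are not given in the sources used here. The authors deposited one table of normalized read counts (a signal on a linear scale, never negative) for 14178 Ensembl gene identifiers and 6 samples. Each column belongs to 1 sample, and its name matches that sample's description.

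The deposited values are not whole reads. Among values under 20, at most 23.1% in any column were whole multiples of one step within a tolerance of 0.1 of the step, where chance alone gives about 20%. The sequencing depth of each library is therefore unknown, no counting interval was given, and no count model was run. Every gene in the table reaches a value of at least 5.52 in some sample, and the lowest mean over the 6 samples is 1.75, so the table holds detected genes only. Columns total 9120292 to 9262064 normalized read counts. No pair of columns is identical. Whether 2 columns agree within sampling noise could not be tested without read counts.

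Values were taken to log2(value + 1) and tested with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, no covariate and all 6 samples. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 14178 genes, with a threshold of 0.05. The planned minimum mean of 1 removed 0 genes. A log2 fold change is RO48 minus DMSO on the log2(value + 1) scale. The pseudocount pulls the fold change of low genes toward 0. The fit averages log values, so where 1 sample of a group is very low, a fitted fold can still exceed the ratio of the group means. The labels give no sign that samples of 1 group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. Libraries were also compared by principal components and by correlations of the same log2 values. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

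The design, the alternatives and 42 gene lists (axon growth, signalling, metabolism, stress, and markers of other cell types) were fixed before the data were examined, with a count test for the case that the table held counts and limma for normalized values; the latter applied. The table gives Ensembl identifiers without gene names, and 0 of the 14178 identifiers matched the reference table of 47357 rat genes used here, which pairs symbols with other kinds of accession. No gene could be named, so 0 of the 42 lists were tested, and no property of the genes such as length or position was used. The rule for named genes took those with the most extreme fold change in each direction among genes with an adjusted p under 0.05, with all 3 RO48 values on one side of all 3 DMSO values and a mean of at least 5 in the higher group. It was limited to 2 identifiers in each direction, and its condition on gene symbols could not be applied.

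The alternatives fixed in advance that could be run were scaling to equal totals, median-of-ratios size factors, pseudocounts of 0.1 and 5, no filter, a minimum mean of 5, stricter thresholds, the replicate number as a block, and leaving out each sample in turn. Alternatives that need counts were not run. A test of RO48 minus DMSO within each replicate number on the linear scale, divided by the gene's mean over the 6 samples, was added after the data were seen. The main fit was tested on simulated data with the real genes' levels and spreads and 6 independent samples, in which 50 genes each were changed by 0.25, 0.5, 1 and 2 on the log2 scale. It recovered 42%, 62%, 86% and 94% of them, respectively, with 4 false calls among 146. In the real data same-numbered samples deviated in opposite directions, which this simulation left out, and far more genes were called. Its false calls therefore do not give the error rate of the real calls. The added pair test recovered 64%, 70%, 94% and 94% of the genes changed by these amounts, on simulated values with a shift per replicate number. It made 7 false calls among 168. The simulated shift was the same in both samples of a number, so it largely cancels in the pair differences. It also made same-numbered samples deviate together, unlike the real ones. The false calls of the pair test therefore do not give the error rate of its real calls either. The simulated noise had an SD equal to the square root of the gene's mean, not the real genes' spreads. The shares recovered by the main fit and by the pair test therefore cannot be compared.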

Results

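Gene expression was profiled in cultured rat embryonic hippocampal neurons after 48 h with RO48 or vehicle. RO48 is an experimental kinase inhibitor that promotes the outgrowth of neurites, the axons and dendrites that young neurons extend in culture. It was used at 10 µM, and the control cultures received 0.025% DMSO. Both were added 3 h after plating. Each group had 3 samples, numbered 1 to 3 in the labels. The deposited normalized read counts covered 14178 genes. They totalled between 9203846 and 9262064 in the DMSO samples and between 9120292 and 9196873 in the RO48 samples. The sequencing depth behind them is unknown. The 10 most abundant genes held 5.08% to 5.29% of a sample's total, so no sample was dominated by a few genes. Genes are given by Ensembl identifier because the table pairs none with a name.

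The first question was whether the samples separated by treatment. They did so along the first principal component, which held 77.9% of the variance. The DMSO samples lay between -33.9 and -30.9 on it, and the RO48 samples between 31.8 and 32.1. Pearson correlations of log2 values across genes were 0.995 to 0.996 between samples of the same group (6 pairs). They were 0.970 to 0.976 between samples of different groups (9 pairs). Genes are not independent replicates, so these values describe the libraries and carry no test. The second component, with 10.1% of the variance, placed DMSO sample 1 at 16.2 and RO48 sample 1 at -15.8, at opposite ends. DMSO samples 2 and 3 lay at -4.2 and -11.4, and RO48 samples 2 and 3 at 4.9 and 10.3. Each number was thus mirrored between the groups.

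The comparison of RO48 with DMSO asked which transcripts had changed after 2 days of inhibitor. The level of 8154 genes, 57.5% of those measured, differed between the groups. Of these, 4127 rose and 4027 fell (limma, adjusted p under 0.05, 3 samples against 3). This fit takes the 6 samples as independent, which the values went against, as described below. With the replicate number as a block, 6563 genes passed, of which 3270 were higher and 3293 lower. Most of the changes were small. The median log2 fold change was 0.35 among the genes that rose and -0.35 among those that fell, with a median standard error of 0.06 among the called genes. A change of less than 1.2-fold was found for 1441 of the rises and 1476 of the falls. At least 2-fold changes were found for 500 rises and 559 falls, and at least 4-fold changes for 64 rises and 67 falls. The other 6024 genes did not pass the threshold, with a median absolute log2 fold change of 0.08. The median log2 fold change over all genes was 0.01.

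**Figure D1:**
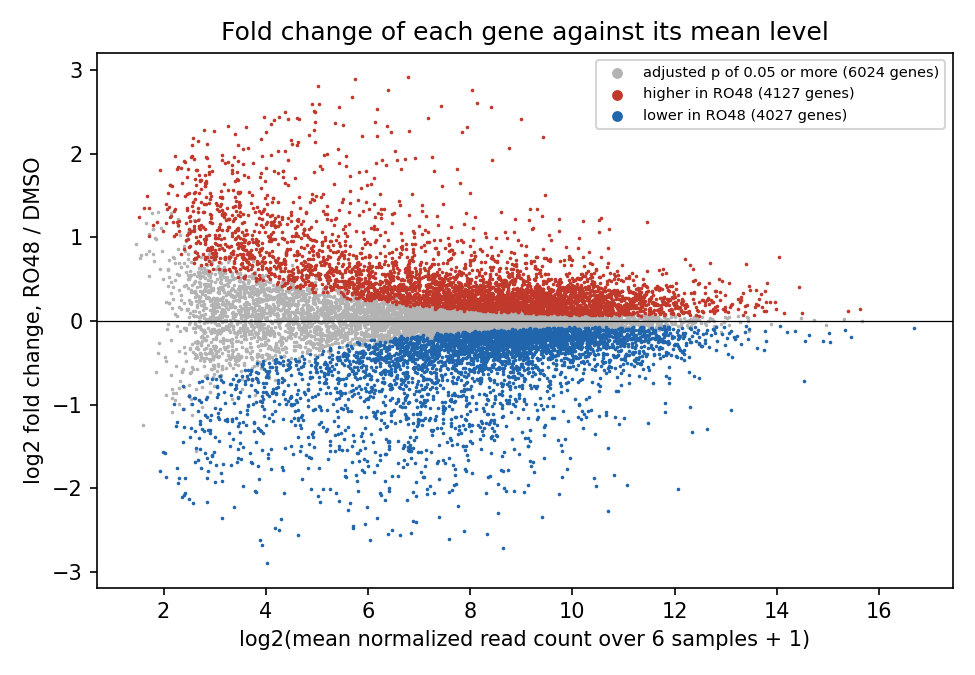
The log2 fold change of RO48 over DMSO (vertical axis) against the log2 mean normalized read count plus 1 over the 6 samples (horizontal axis), 1 point per gene. The 4127 genes that rose are red, the 4027 that fell are blue and the 6024 that did not pass the limma test are grey; among large changes, rises lie mostly at low levels and falls extend over the whole range.

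The genes that rose made up 32.3% ± 0.507 (SD, n = 3) of the total in DMSO samples and 39.4% ± 0.252 (SD, n = 3) in RO48 samples. The genes that fell made up 39.5% ± 0.566 (SD, n = 3) in DMSO samples and 32.2% ± 0.324 (SD, n = 3) in RO48 samples. These genes were chosen for their change in the same samples, so the shares describe its size and were not tested. In 8820 genes, or 62.2%, the 3 RO48 values lay all above or all below the 3 DMSO values, where chance gives 10% for independent samples. Chance would give 25% if the mean of each same-numbered pair had been removed from the values in full. That was not the case here, since the sums of same-numbered samples still varied between numbers. Among the 8154 called genes, 281 had groups that overlapped.

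Abundant transcripts passed the test often, mostly with small changes. Of the 100 most abundant genes, which held 17.1% of all normalized read counts, 48 rose, 33 fell and 1 passed the test with an at least 2-fold change. Genes were then split by mean level over the 6 samples into 5 classes of equal size, a split chosen after the values were seen. In the most abundant class, 73.6% of the genes passed the threshold, and 2.25% of those changed at least 2-fold. In the least abundant class, with means of 1.75 to 37.9, 41.5% passed and 46.2% of those changed at least 2-fold. All these counts come from the fit that takes the samples as independent, whose standard errors are too small, as described below. The share that passed under the block was not counted for the most abundant class. The median standard error of the log2 fold change was 0.22 in the least abundant class and 0.03 in the most abundant one. A change thus had to be larger to pass in the least abundant class. The shares that passed, and the sizes of the called changes, therefore depend on this precision. They do not show that abundant and scarce transcripts responded differently.

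The balance of rises and falls was also counted in each class, without a test of the difference between classes. In the least abundant class 786 genes rose and 391 fell, so that rises were 66.8% of the called genes. With the replicate number as a block, the counts in this class were 503 and 249, and the share of its genes that passed was 26.5%. Rises were 49.0%, 46.0% and 45.0% of the called genes in the next 3 classes, in order of rising level. In the most abundant class 1063 genes rose and 1023 fell, so that rises were 51.0%, and the shares followed no steady trend with level. Over the 4 classes above the least abundant one, rises were 47.9% of the called genes. They were 50.1% there after scaling to equal totals and 46.3% with median-of-ratios size factors, so this balance depended on the scaling. Among at least 2-fold changes, 364 rose and 180 fell in the least abundant class, while 136 rose and 379 fell in the other 4 classes. In the most abundant class, 8 genes rose and 39 fell by at least 2-fold.

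The 2 genes with the largest fitted rises and the 2 with the largest fitted falls are given here; within each direction their order turned under some alternative settings. ENSRNOG00000029342 rose from 26.9 ± 15.9 normalized read counts in DMSO to 192 ± 37.8 in RO48 (SD, n = 3 each). Its log2 fold change was 2.92 with a standard error of 0.31 (limma adjusted p = 1.8e-05). ENSRNOG00000015049 rose from 15.1 ± 11.0 to 90.2 ± 24.9 normalized read counts (SD, n = 3 each), a log2 fold change of 2.89 with a standard error of 0.58 (limma adjusted p = 0.00156). DMSO sample 1 held 2.45 of this gene against 22.7 and 20.2 in the other DMSO samples, and without it the log2 fold change was 1.99. RO48 sample 1 held the highest RO48 value of this gene, 119. ENSRNOG00000006019 fell from 26.6 ± 7.70 to 3.68 ± 3.06 normalized read counts (SD, n = 3 each). Its log2 fold change was -2.90 with a standard error of 0.57 (limma adjusted p = 0.00128). DMSO sample 1 held its highest DMSO value, 35.5. RO48 sample 1 held 0.145 of it, and without that RO48 sample the log2 fold change was -2.07. It was -3.73 with a pseudocount of 0.1 and -1.91 with a pseudocount of 5. ENSRNOG00000042140 was far more abundant and fell from 687 ± 79.9 to 109 ± 40.0 normalized read counts (SD, n = 3 each), a ratio of means of 0.158. Its log2 fold change was -2.71 with a standard error of 0.22 (limma adjusted p = 2.39e-06). These adjusted p-values take the samples as independent. In limma with the replicate number as a block, they were 0.000216, 0.00407, 0.00466 and 4.18e-05, in the order given.

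**Figure D2:**
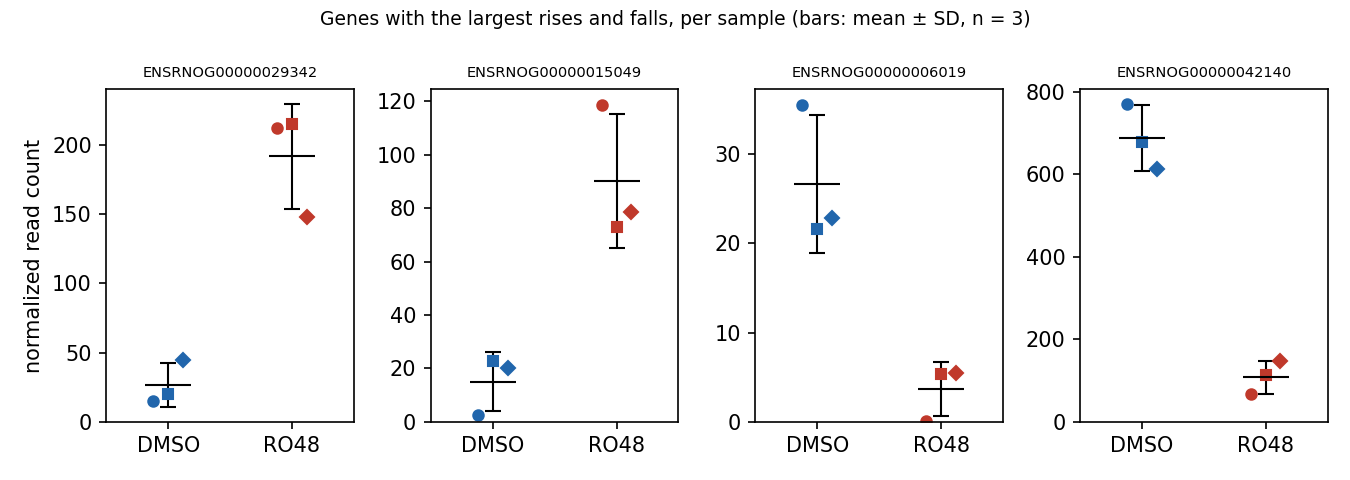
Normalized read counts (vertical axes, linear, starting at 0) of the 2 genes with the largest fitted rises and the 2 with the largest fitted falls, per sample, in DMSO (blue) and RO48 (red); circles, squares and diamonds are samples 1, 2 and 3, and bars show the mean and SD (n = 3). Both groups are apart in all 4 genes, and RO48 sample 1 is close to 0 for ENSRNOG00000006019, at 0.145.

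The spread between samples of a group was not independent between the groups. Across 12218 genes with a mean of at least 20, the deviation of a DMSO sample from its group mean correlated with that of the RO48 sample of the same number at -0.60, -0.52 and -0.52 for numbers 1, 2 and 3. For samples with different numbers the correlations ranged from 0.05 to 0.44. Among 756 genes with a mean under 8 and no value of 0, the values of same-numbered samples lay within 0.02 of each other for 42, 39 and 46 genes, and those of differently numbered samples for 1 to 5 genes. Deviations within a group of 3 sum to 0, which ties the correlations of differently numbered samples to those of same-numbered ones. The p-values above treat the 6 samples as independent. Opposite deviations of same-numbered samples make the standard errors and p-values of that fit too small. With the replicate number as a block, 6563 genes passed.

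**Figure D3:**
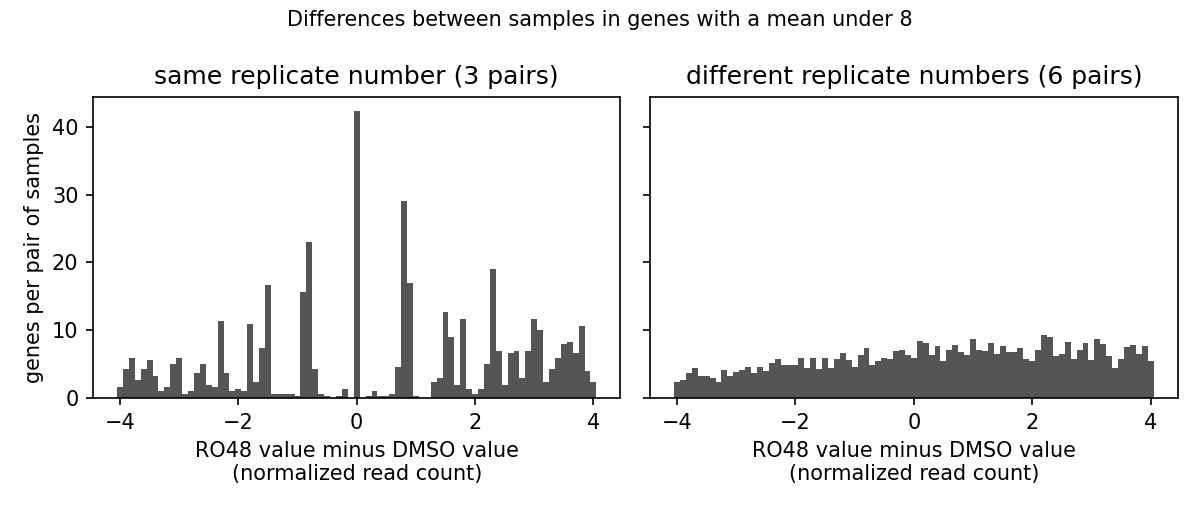
Differences between an RO48 and a DMSO sample (horizontal axis, normalized read counts, between about -4 and 4) in the 756 genes with a mean under 8 and no value of 0, as the number of genes per pair of samples (vertical axis), for the 3 same-numbered pairs (left) and the 6 differently numbered pairs (right). Part of the same-numbered differences cluster at 0 and at separated steps, while differences between differently numbered samples show no such clusters.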

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

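The alternatives changed how many genes passed the test, but no gene called in both the main fit and an alternative changed direction. Genes that lost their call were not compared. The small excess of rises over falls among all called genes did turn under some alternatives. With median-of-ratios size factors, for example, 4005 genes were higher and 4148 lower. Apart from a 2-fold minimum, which left 500 genes higher and 559 lower by its own construction, each alternative kept both counts over all genes within 1.5 times the reported 4127 and 4027. Leaving out 1 sample gave 3602 to 3947 genes higher and 3588 to 3901 lower. With the replicate number as a block, 3270 genes were higher and 3293 lower, and 6559 of the 8154 called genes kept their call and direction. Of the 1059 genes called with at least a 2-fold change, 1000 remained called under the block. No label says what a number marks, so the block was an alternative. Same-numbered samples did not deviate together, but removal of an effect of the number before deposit would leave opposite deviations, so their sign does not argue against a shared origin. The pair differences on the linear scale, added after the data were seen, gave 3245 higher and 3276 lower. In the least abundant class the counts fell from 786 higher and 391 lower to 503 and 249 under the block, and to 495 and 247 in the pair differences; the cause was not tested. Leaving out 1 sample gave 663 to 714 higher and 315 to 350 lower in that class. Scaling to equal totals or by the median of ratios moved the median log2 fold change by 0.01 at most, and rises were 52.6% and 49.1% of the called genes, against 50.6%. All 4 genes given by identifier kept their direction and their call under every alternative run. The first principal component held 87.1% of the variance over the 500 most variable genes and 78.8% to 80.2% without 1 sample. The test without a filter is void, since the filter removed 0 genes. The depth of the libraries is unknown, so what it limits could not be computed.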

Other observations

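Tests chosen only after their result was seen were the count of near-equal low genes, the check of columns for whole multiples, and the count of sample splits. The test on genes with an unadjusted p above 0.5 was set before its result was seen. So were both tests on the least abundant class. The patterns that these tests bear on had, however, been found in the same data.

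Samples with the same number in both groups deviated from their group means in opposite directions. One scale factor per library and nothing else would leave each column as whole multiples of one step, and it is argued against by the values under 20, of which at most 23.1% in any column were such multiples against 20% by chance. A response to RO48 that was stronger in some replicates would place the relation in responding genes. Over 1624 genes with an unadjusted p above 0.5, however, the mean same-numbered correlation was -0.602. A high p does not show that a gene did not respond, and it also picks genes with a large spread within the groups. A candidate explanation is that a shift per gene and replicate number was made on the linear scale before deposit, since such a shift leaves the difference within a number untouched: at least 39 low genes were near-equal in each same-numbered pair, against at most 5 in any other pair. Whatever the cause, opposite deviations make the standard errors of a test on 6 independent samples too small. The differences within a number call 6517 of the 8154 genes in the same direction. Under the hypothesis of a shift, they are the part of the table that such a shift does not alter.

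In same-numbered pairs the low-gene differences also fell on steps. The strongest step was 0.873 for number 1, 0.749 for number 2 and 0.741 for number 3, with a periodicity (from 0 for none to 1 for exact) of 0.397, 0.478 and 0.428. It was at most 0.093 in differently numbered pairs. Spread was measured as the squared change from one number to another divided by the gene's mean. Its median over genes was averaged over the pairs of numbers. This measure was 2.68 to 3.70 times as large for same-numbered differences as for same-numbered sums, over the 3 ranges of level between 10 and 1000.

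In the least abundant class, more of the called genes rose than fell. Whether the scaling between libraries plays a part cannot be told: rises were at least 66.1% of the called genes of this class under both other scalings, but these moved the median log2 fold change by 0.01 at most, too little to test it. Whether the log scale acting on a shift per replicate number plays a part cannot be told either. Rises were 66.7% in the pair differences on the linear scale. A shift shared by both samples of a number leaves the sign of their difference unchanged on either scale. The share of rises could thus hardly move, and its value decides nothing. The authors' filter for detected genes could not be examined with the table used here. The treatment itself, which may have raised many scarce transcripts, stays open as an untested hypothesis. The classes were set by the mean over all 6 samples, not by the level in control neurons.

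The 6 samples can be split into 3 and 3 in 10 ways. The real split gave 8154 genes past the threshold and the highest of the others gave 0, so 1 of the 10 splits gave as many. With 10 splits no share under 0.05 can be reached. Every other split mixes both treatments in each group, which puts the treatment difference into the spread. Its low count was thus largely fixed in advance and gives no level for chance. The splits also treat the samples as exchangeable, although same-numbered samples deviated in opposite directions.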
